A study of Arabidopsis thaliana with 12 samples.

How the data were processed

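The deposited values are log2 intensities from RMA, per the submitters' processing notes, which name R 2.11. The labels describe total RNA from whole seedlings, extracted with Trizol and cleaned on a column, and biotin-labelled aRNA made by the 3' IVT protocol. Such labelling starts from poly(A) tails, so values of chloroplast-encoded transcripts depend on the few that carry a tail. Scan dates and labelling batches are not given in the sources used here. The value table held 22810 probe sets for 12 arrays, with 0 missing values and 0 pairs of identical arrays. No values were changed before testing.

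The 64 Affymetrix control probe sets were left out of all tests and used only to describe the arrays. Of the 22746 probe sets tested, 13513 were assigned to 1 gene, 503 to several and 8730 to none. All were kept in the tests, and only those of 1 gene were named. A RefSeq table of TAIR10.1 matched 13436 of the 13513, and 11933 go by locus identifier only. The probe assignments cover 13355 distinct genes, and coordinates were not used.

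Each probe set was fitted with limma's linear model with 1 mean per genotype over all 12 arrays, and comparisons were taken as contrasts. Empirical Bayes moderation used the default prior, with 8 residual and 4.43 prior degrees of freedom. P-values are two-sided and were adjusted within each comparison by the Benjamini-Hochberg method, with adjusted p under 0.05 as the threshold. The 6 comparisons are each mutant with wild type and each pair of mutants. The comparisons, the test, the threshold, 22 gene lists and a set of alternatives were chosen before the data were examined.

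Of the 415 list members, 56 had a probe set assigned to that gene alone, and only these are called measured here. Whether others lie among the 8730 probe sets with no gene assigned, or the 503 with several, was not examined. Lists of ABA and cold (4 of 29), auxin (8 of 20), cytosolic ribosomal (8 of 24), flavonoid and anthocyanin (5 of 22), heat shock (6 of 19), photosynthesis (5 of 32), root marker (4 of 15) and salicylate defence genes (3 of 25) had at least 3 measured. These 8 were tested with camera, with a preset correlation of 0.01 between genes and 1 probe set per gene, the brightest. Adjustment covered all 24 list tests, and each was repeated with the correlation estimated from the data. Another 10 lists had 1 or 2 measured members and were read gene by gene. The MBD family, phosphate starvation, morning clock and sugar starvation lists had 0 measured members and gave no result. A test of transposable element genes was planned for 20 or more probe sets and was not run, because 0 had such annotation text.

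Further lists were chosen after values were seen: low-oxygen, chloroplast-encoded, mitochondrion-encoded, class III peroxidase, extended iron, extended cytosolic ribosomal, nuclear chloroplast ribosomal, core histone and pseudogene lists, and 28 families of shared gene symbol with at least 8 probe sets. They were tested with camera in the same way and adjusted over 111 tests. The result of 1 of these families is not reported here.

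Genes were named by a rule. For each mutant against wild type it took the 12 largest rises and 12 largest falls among called probe sets of 1 gene whose 3 mutant and 3 wild-type values did not overlap, keeping the larger change where a gene had a pair of probe sets. It took 3 per direction between mutants, and 8 per direction with the largest smallest change among genes called alike in all 3 mutants. It added up to 4 members of a list that passed, or that moved in the direction of a list call. The texts name part of these. The genes of the figure of single genes were chosen after the values were seen.

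Expected shared calls are products of call counts, per direction, divided by the number of probe sets. Counts of calls in all 3 mutants without each wild-type array were added after the data were seen. Simulations of shared wild-type arrays drew 100 data sets with each genotype's spread and no change. A further simulation added changes of log2 0.5, 1 and 2 to 200 probe sets, and of 0.5 to 20 members of a list. In each comparison 66, 67 and 67 of the 200 had changes of 0.5, 1 and 2. Of these, the test recovered 12.1%, 59.7% and 95.5% in mbd4, 13.6%, 52.2% and 92.5% in mbd6, and 31.8%, 79.1% and 97.0% in mbd11. The recovery in mbd11 came with 388 false calls among its 534 simulated calls, so it does not show a better test there. Versions were R 4.3.3, limma 3.58.1, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.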

Results

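The series held 12 arrays of 10-day-old Col-0 seedlings grown on MS medium, 3 each of wild type and of the T-DNA mutants mbd4, mbd6 and mbd11. The mutated genes encode methyl-CpG-binding domain proteins. The question the labels give is which transcripts change when each of these genes is disrupted. Transcripts of MBD4, MBD6 and MBD11 themselves were not analysed here, because no probe set was assigned to any of the 3 genes alone. Values are deposited log2 intensities, each change is mutant minus wild type in log2 units, and n = 3 in each group throughout. The p-values of single probe sets measure a change against the moderated spread within genotypes. That spread is pooled over the 4 genotypes and 12 samples, or over fewer where arrays were left out. Without weights the fit assumes the same spread in every genotype, and mbd11 had a wider one. The camera p-values of lists compare the genes of a list with other genes. They therefore depend on the spread between genes as well, and on the correlation assumed between them.

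The arrays of mbd11 stood apart from the other 9. Correlations between mbd11 arrays and the others ran from 0.900 to 0.960, while the lowest correlation among the other 9 arrays was 0.979. The interquartile range of log2 values was 3.63, 2.83 and 3.58 in the 3 mbd11 replicates and 3.83 to 3.90 in wild type. The difference between 3' and 5' probe sets of plant control transcripts averaged 1.98, 1.99 and 2.58 in mbd11. The same measure was 1.17, 1.5 and 1.18 in wild type and 1.2 to 1.3 in mbd6. In mbd4 it was 1.08, 1.15 and 2.08, the last value belonging to replicate 3. The median SD of a probe set within a group was 0.353 in mbd11, against 0.112 in wild type, 0.134 in mbd4 and 0.118 in mbd6.

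**Figure D1:**
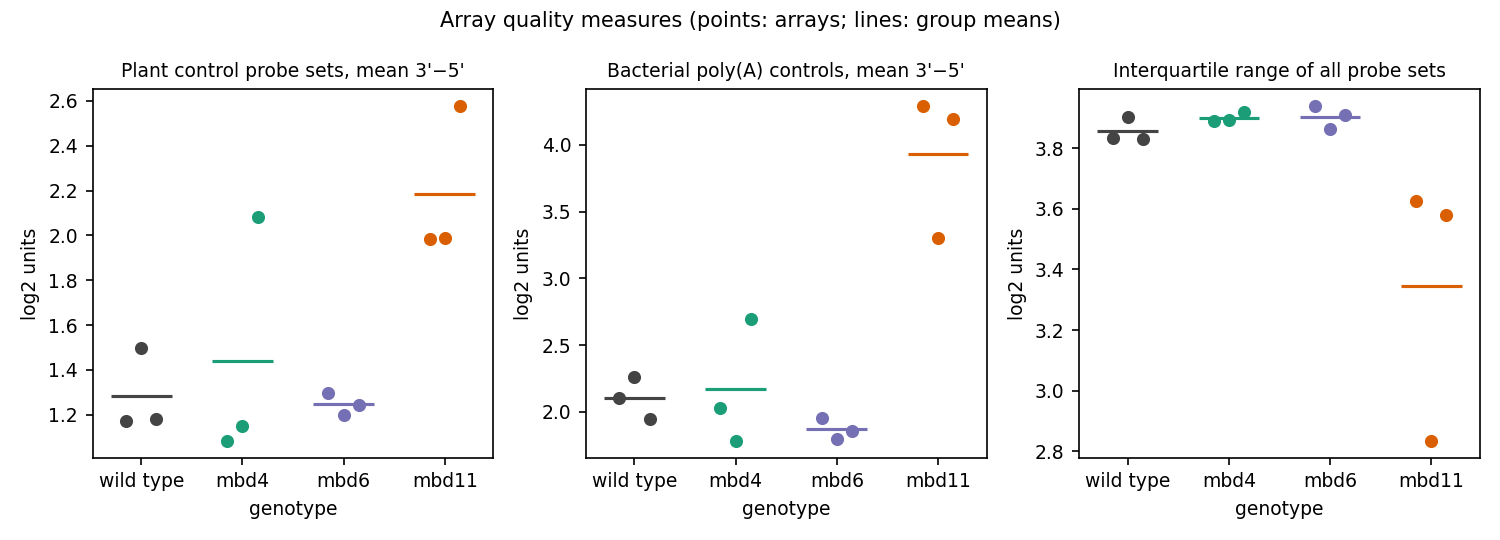
Each point is an array, and lines are group means (n = 3). Panels show the mean 3' minus 5' log2 difference of plant control probe sets, the same for the bacterial poly(A) controls dap and thr, and the interquartile range of log2 values; mbd11 replicate 2 has the narrowest range at 2.83.

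In mbd4 against wild type AT5G24240 rose the most on the values as deposited, from 3.82 (SD 0.04) in wild type to 7.72 (SD 0.15), a change of 3.89 or 14.9-fold (adjusted p = 7.9e-07). It was under 4 on all wild-type arrays, and with values under a floor of 4 raised to it the change was 3.72. AT1G19530, with all values above 4, rose by 3.85, from 4.75 (SD 0.25) to 8.59 (SD 0.11, adjusted p = 9.4e-06). The plant defensin gene PDF1.2 rose by 3.72, from 7.88 (SD 0.07) to 11.59 (SD 0.08; adjusted p = 8.6e-06). AT1G33055 rose by 3.39, from 5.27 (SD 0.07) to 8.66 (SD 0.23; adjusted p = 7.8e-05). DFR, the dihydroflavonol reductase gene of anthocyanin synthesis, rose by 2.24, from 6.63 (SD 0.03) to 8.87 (SD 0.15; adjusted p = 0.00579). AT2G15880, AT1G17640, AT4G22470, AT4G10270 and AT1G08310 rose by 2.78, 2.77, 2.66, 2.32 and 2.22. AT2G15880 was under 4 on all wild-type arrays, and with a floor of 4 it rose by 2.218. AT4G33720 rose by 3.35, from 5.85 (SD 0.15) to 9.20 (SD 0.06; adjusted p = 0.0118), a call lost without wild-type replicate 1 or 2 (adjusted p = 0.060 and 0.055) or mbd4 replicates 1, 2 or 3 (0.053, 0.054 and 0.052; 3.5e-10 to 0.0598 over all alternatives). PDF1.2b rose by 3.05, on a probe set whose design allows hybridization of related transcripts. The osmotin-like gene OSM34 rose by 1.99 (adjusted p = 5.8e-05).

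The largest fall in mbd4 was that of AT4G33550, by 2.64, from 8.26 (SD 0.12) to 5.62 (SD 0.33; adjusted p = 0.00016). AT1G76960 fell by 1.78, M10 by 1.56, AT5G03350 by 1.5, AT4G35720 by 1.44 and AT2G40460 by 1.37. The cold-regulated gene COR15A fell by 1.49, from 8.15 (SD 0.02) to 6.66 (SD 0.11; adjusted p = 0.00105). For each gene named as risen or fallen in mbd4 the 3 mutant and 3 wild-type values did not overlap, which the naming rule required of the largest changes.

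Over all 22746 probe sets, limma's moderated test called 523 in mbd4 at an adjusted p under 0.05, 348 higher and 175 lower. Of these, 263 changed at least 2-fold. The 3 mutant and 3 wild-type values did not overlap for 28.5% of all probe sets, where 10% would do so by chance. The count fell when a single array was left out: 265, 281 and 259 without wild-type replicates 1, 2 and 3, and 288, 276 and 311 without mbd4 replicates 1, 2 and 3. Without mbd11 replicate 2 it was 1464, with 817 higher and 647 lower. Without all mbd11 arrays it was 2212, with 1171 higher and 1041 lower, and all 523 were among them in the same direction. The median change of all probe sets was -0.03.

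In mbd4 the 4 measured ABA and cold genes had a median change of -0.73, and 3 of them fell (3 of 4 also when adjusted over the list alone; camera adjusted p = 2.4e-06; 0.0418 with an estimated correlation, and 3.9e-07 to 0.0418 over all alternatives). Beside COR15A these were COR15B, which fell by 0.92 (adjusted p = 0.00636), and COR47, which fell by 0.54 (adjusted p = 0.0219). The COR47 call was lost without any 1 of the wild-type arrays (adjusted p = 0.074, 0.115 and 0.122 for replicates 1 to 3) or the mbd4 arrays (0.079, 0.125 and 0.062; 9.1e-05 to 0.125 over all alternatives). LTI30 differed by -0.25 (adjusted p = 0.601).

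The 5 measured flavonoid and anthocyanin genes had a median change of 1.1 in mbd4 (camera adjusted p = 0.00033; 0.152 with an estimated correlation, and 1.0e-06 to 0.152 over all alternatives). DFR alone passed over all probe sets, and 3 passed when adjusted over the list alone. AT4G14090 differed by 1.36 and UF3GT by 1.1 without passing (adjusted p = 0.146 and 0.166). AT4G14090 passed without mbd4 replicate 3 (adjusted p = 0.037; 0.000188 to 0.475 over all alternatives) and UF3GT without mbd6 replicate 1 (0.017; 0.00113 to 0.498 over all alternatives). Heat shock genes had a median of 0.54 over 6 (camera adjusted p = 0.00311; 0.0624 with an estimated correlation, and 0.000454 to 0.0624 over all alternatives). Among them AT5G51440 rose by 1.78 (adjusted p = 0.00735), the single call over all probe sets beside 3 over the list alone. The 3 salicylate defence genes had a median of 0.31 (camera adjusted p = 0.0179; 0.0939 with an estimated correlation, and 0.00305 to 0.0939 over all alternatives). The transcription factor gene WRKY53 rose by 1.01 (adjusted p = 0.0237), the only call in either count. That call was lost without wild-type replicates 1, 2 or 3 (adjusted p = 0.090, 0.086 and 0.128) or mbd4 replicates 1 or 3 (0.118 and 0.118; 0.000172 to 0.128 over all alternatives). Photosynthesis, cytosolic ribosomal, auxin and root marker lists had medians of -0.15, 0.05, 0.17 and 0.02 with 0 calls each, over all probe sets or over the list (camera adjusted p = 0.154, 0.333, 0.064 and 0.582). The auxin list passed without wild-type replicate 3 (adjusted p = 0.0365; 0.0365 to 0.178 over all alternatives).

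In mbd6 against wild type AT4G33720 rose by 4.12, from 5.85 (SD 0.15) to 9.97 (SD 0.10; adjusted p = 0.00151). PDF1.2 rose by 3.64, from 7.88 (SD 0.07) to 11.52 (SD 0.43), or 12.5-fold (adjusted p = 4.4e-06). OSM34 rose by 2.73, from 9.10 (SD 0.10) to 11.84 (SD 0.19; adjusted p = 3.2e-06). AT3G19680 rose by 3.03 (adjusted p = 7.7e-06), AT1G26250 by 2.91, AT1G08310 by 2.79, AT4G16260 by 2.64, AT5G20790 by 2.55 and AT5G40590 by 2.46. AT1G26250 was under 4 on all wild-type arrays, and with a floor of 4 it rose by 1.98. The transporter gene OCT1 rose by 2.47 and the cytochrome P450 gene CYP71B22 by 2.43. PDF1.2b rose by 2.96.

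In mbd6 AT1G47400 fell the most; it fell by 4.18, from 11.11 (SD 0.16) to 6.92 (SD 0.45; adjusted p = 7.2e-05). The iron-deficiency transcription factor genes BHLH101 and PYE fell as well. BHLH101 fell by 2.85, from 8.88 (SD 0.07) to 6.03 (SD 0.57; adjusted p = 0.00234). PYE fell by 2.09, from 7.92 (SD 0.10) to 5.84 (SD 0.12; adjusted p = 0.000269). AT3G28220, AT3G28270, AT5G42760, AT1G60590, AT1G73120 and AT2G15020 fell by 2.64, 2.35, 2.32, 2.32, 2.1 and 2.1. Chloroplast-encoded photosynthesis genes were among the largest falls: psbI by 3.06, from 9.02 to 5.96 (SD 0.88; adjusted p = 0.0002), psbK by 2.96 and atpA by 2.36. By the naming rule, the 3 mutant and 3 wild-type values of the genes named as risen or fallen in mbd6 did not overlap.

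The moderated test called 1572 probe sets in mbd6, 910 higher and 662 lower, with 631 changed at least 2-fold. The 3 mutant and 3 wild-type values did not overlap for 36.1% of all probe sets, beside 10% by chance. Leaving out wild-type replicates 1, 2 or 3 gave 859, 901 and 807 calls. Leaving out mbd6 replicates 1, 2 or 3 gave 887, 977 and 945, and leaving out mbd11 replicate 2 gave 3155. Without all mbd11 arrays the count was 4106, with 2070 higher and 2036 lower, and all 1572 were among them in the same direction. The median change of all probe sets was -0.03.

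Salicylate defence genes had a median change of 0.99 over 3 in mbd6 (camera adjusted p = 0.000779; 0.0518 with an estimated correlation, and 6.8e-05 to 0.0518 over all alternatives). WRKY53 rose by 1.42 (adjusted p = 0.00142) and GRX480 by 0.99 (adjusted p = 0.018), and all 3 passed over the list alone. The GRX480 call was lost without wild-type replicate 1 or 2 (adjusted p = 0.070 and 0.089) or mbd6 replicate 1 (0.063; 0.000643 to 0.0895 over all alternatives). SAG101 differed by 0.49 (adjusted p = 0.218) and passed without mbd11 replicate 2 (0.037; 0.00716 to 0.598 over all alternatives). The 4 ABA and cold genes had a median of -0.25 (camera adjusted p = 0.0179; 0.131 with an estimated correlation, and 0.00257 to 0.131 over all alternatives), and COR15A fell by 1.02 (adjusted p = 0.00582), the only call in either count. COR15B, COR47 and LTI30 differed by -0.27, -0.23 and -0.19. The ABA and cold call was lost without mbd6 replicate 2 (adjusted p = 0.0529).

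Flavonoid and anthocyanin genes had a median of 0.67 over 5 in mbd6 (camera adjusted p = 0.0392; 0.327 with an estimated correlation, and 0.0069 to 0.327 over all alternatives). DFR rose by 1.83 (SD 1.02; adjusted p = 0.00946), the single call beside 2 over the list alone. This list call was lost without wild-type replicate 2 (adjusted p = 0.0656), mbd6 replicate 1 (0.239, with a median of 0.17) or mbd11 replicates 1, 2 or 3 (0.0709, 0.0715 and 0.0621). Heat shock, auxin and root marker genes had medians of 0.32, 0.05 and 0.33 (camera adjusted p = 0.162, 0.190 and 0.0931). The root marker list passed without mbd6 replicate 1 (adjusted p = 0.0464; 0.0253 to 0.181 over all alternatives). The auxin-conjugating gene WES1 rose by 1.14 (adjusted p = 0.000566) and was the only auxin call. Over the list alone each of these 3 lists had 1 call. Photosynthesis and cytosolic ribosomal genes had medians of -0.02 and -0.16 with 0 calls in either count (camera adjusted p = 0.517 and 0.162).

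A list of chloroplast-encoded genes was chosen after the values were seen. Its 69 genes had a median change of -0.84 in mbd6, with 16 lower and 0 higher (camera adjusted p = 5.1e-17; 0.655 with an estimated correlation). The gene rbcL, for the large Rubisco subunit, fell by 1.43 (adjusted p = 0.0025). In mbd4 the median was -0.08 with 0 calls (camera adjusted p = 0.711). The 25S rRNA control probe set averaged 6.59 in mbd6, 8.35 in mbd4 and 7.11 in wild type, with single wild-type arrays at 5.64 to 7.90.

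In mbd11 against wild type, 10 of the 12 largest falls among called probe sets of 1 gene without overlap were in chloroplast-encoded genes. The ndhA gene fell by 4.98, from 11.43 (SD 0.03) to 6.45 (SD 0.11), or 31.5-fold (adjusted p = 3.1e-09). The rpl36 gene fell by 4.8, from 11.44 to 6.64 (SD 0.82). Falls of atpA, psbH, petB, rpl22, cemA, rpl14 and psbL were 4.01, 3.81, 3.71, 3.37, 3.32, 3.20 and 3.13. The nuclear genes were AT5G13030, which fell by 3.5, and the glycosyl hydrolase gene GH9C2, which fell by 3.18. Photosystem I gene psaA differed by -3.63 (adjusted p = 0.0238), a call lost without wild-type replicate 1 or 3 or mbd11 replicate 1 (adjusted p = 0.083, 0.081 and 0.058; 0.000419 to 0.997 over all alternatives). With the plant 3' minus 5' difference as a covariate psaA differed by 0.0074 (adjusted p = 0.997).

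AT4G27280 rose the most in mbd11, by 3.48, from 9.16 (SD 0.09) to 12.64 (SD 0.58), or 11.2-fold (adjusted p = 1.5e-06). The expansin-like gene EXLA1 rose by 3.33, from 5.39 to 8.72 (SD 0.79). AT2G15010 also rose by 3.33, with an SD of 1.93 among the mutant arrays (adjusted p = 0.00153), a call lost with the plant 3' minus 5' difference as covariate, at 2.79 (adjusted p = 0.0631; 3.3e-09 to 0.0631 over all alternatives). AT2G15010 was under 4 on all wild-type arrays, and without mbd11 replicate 2 it rose by 4.43. AT5G10695, AT4G10270, AT3G19680, AT1G15010, AT2G01300, AT1G33055 and AT1G05575 rose by 2.94, 2.88, 2.85, 2.81, 2.80, 2.77 and 2.72. The 3 mutant and 3 wild-type values of each gene named as largest in mbd11 did not overlap, as the naming rule required.

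The moderated test called 9141 probe sets in mbd11, 4649 higher and 4492 lower, and 8653 of them showed no overlap between mutant and wild-type values. No overlap was seen for 47.7% of all probe sets, beside 10% by chance. At least 2-fold changes numbered 2922, 1127 higher and 1795 lower. The median change of all probe sets was 0.12, and 0.22 after median centring, which gave 5903 higher and 3938 lower. In 5 classes of rising wild-type level the median mbd11 change was 0.40, 0.29, -0.03, -0.23 and -0.38, with 44.9% of the highest class called lower. In simulated data with each group's own spread, where 200 probe sets and 20 members of a list were shifted and 22526 were not, the same test made 388 false calls in mbd11, or 72.7% of its 534 simulated calls. The false calls were 1.72% of the 22526. A share of calls depends on how many probe sets were shifted, so 72.7% is not an estimate for the 9141. For mbd4 and mbd6 the false calls were 8 of 120 and 2 of 110. Only the 6 arrays compared gave 5100 calls in mbd11, and the plant 3' minus 5' difference as covariate 5829. With arrays weighted by the spread of their genotype, 5262 probe sets were called in mbd11, 5225 of them shared in direction with the 9141, and 81 of 171 simulated calls were false. With these weights 69 of 234 simulated calls were false in mbd4 and 37 of 226 in mbd6.

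The 69 chloroplast-encoded genes, a list chosen after the values were seen, had a median change of -1.59 in mbd11, with 45 lower and 4 higher (camera adjusted p = 9.6e-12; 0.71 with an estimated correlation). The median was -1.24 with the plant 3' minus 5' difference as a covariate and -1.34 without mbd11 replicate 2. The 4 that rose were petG, petD, rps14 and petN, by 0.53, 0.98, 1.2 and 1.3. The mbd11 arrays carried a higher 3' minus 5' difference than wild type (1.98 to 2.58 against 1.17 to 1.5). The 25S rRNA control probe set, also of RNA mostly without poly(A) tails, was at 5.25 to 5.43 in mbd11 and 5.64 to 7.90 in wild type.

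Heat shock genes had a median change of 1.34 over 6 in mbd11, with 5 higher in both counts (camera adjusted p = 0.0179; 0.0939 with an estimated correlation, and 6.9e-05 to 0.0939 over all alternatives). AT5G51440, AT2G29500, AT5G48570 and HSA32 rose by 2.42, 1.98, 1.73 and 0.94. The AT5G48570 call was lost with the plant 3' minus 5' difference as covariate, at 0.84 (adjusted p = 0.288), and with only the 6 arrays compared (0.0501; 8.7e-07 to 0.288 over all alternatives). With only those 6 arrays HSA32 lost its call too (adjusted p = 0.0669; 0.000124 to 0.0669 over all alternatives). The nuclear photosynthesis genes had a median of -0.65 over 5, with 4 lower in both counts (camera adjusted p = 0.0179; 0.0939 with an estimated correlation, and 2.0e-05 to 0.0939 over all alternatives). The Calvin cycle genes PRK and RCA fell by 1.24 and 1.03 (adjusted p = 5.7e-05 and 0.000155), and the antenna genes LHCB4.1 and LHCB4.2 by 0.65 and 0.63. The genes PRK, RCA, LHCB4.1 and LHCB4.2 had wild-type values of 12.40, 13.74, 13.09 and 12.66, in the highest class of level, where the median change of all probe sets was -0.38. LHCB4.2 lost its call with weights by genotype (adjusted p = 0.0719) and with that covariate (0.0928; 0.00082 to 0.0928 over all alternatives). The heat shock list call was lost without mbd11 replicate 1 (adjusted p = 0.0678). Plant 3' minus 5' differences of 1.98 to 2.58 in mbd11 and 1.17 to 1.5 in wild type accompany both lists.

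Cytosolic ribosomal genes had a median of -0.42 over 8 in mbd11, with 4 lower and 1 higher, and 5 over the list alone (camera adjusted p = 0.0443; 0.327 with an estimated correlation, and 0.00302 to 0.327 over all alternatives). AT2G41840, AT3G09630, AT5G02870 and PGY1 fell by 1.38, 1.33, 0.95 and 0.66. Their wild-type values ran from 11.24 to 11.86, in the highest class of level, where the median change of all probe sets was -0.38. A wider list of 112 cytosolic ribosomal genes, chosen after values were seen, had 28 higher and 20 lower in mbd11 (camera adjusted p = 0.86). The wider list had a median of 0.03, and -0.03 with 11 higher and 15 lower with the plant 3' minus 5' difference as covariate. The call of the 8-gene list was lost without wild-type replicate 2 (adjusted p = 0.0656), mbd4 replicate 3 (0.0536), mbd6 replicate 2 (0.0514) or mbd11 replicate 1 or 2 (0.0566 and 0.0695). Salicylate defence genes had a median of 1.03 with 3 of 3 higher in both counts (camera adjusted p = 0.0392; 0.131 with an estimated correlation, and 4.8e-05 to 0.131 over all alternatives). WRKY53, GRX480 and SAG101 rose by 1.69, 1.03 and 0.69, SAG101 losing its call without wild-type replicate 3 (adjusted p = 0.061; 0.000263 to 0.391 over all alternatives). SAG101 differed by 0.31 with the plant 3' minus 5' difference as covariate (adjusted p = 0.391) and by 0.40 with quantile normalization (0.306). GRX480 lost its call with weights by genotype (adjusted p = 0.0857; 0.00075 to 0.0857 over all alternatives). The salicylate list call was lost without mbd11 replicate 1 or 3 (adjusted p = 0.0709 and 0.0621). Here too the 3' minus 5' difference was 1.98 to 2.58 in mbd11 and 1.17 to 1.5 in wild type.

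ABA and cold genes had a median of 0.57 over 4 in mbd11, with 2 higher and 4 over the list alone (camera adjusted p = 0.0392; 0.174 with an estimated correlation, and 6.8e-05 to 0.174 over all alternatives). COR47 rose by 1.05 (adjusted p = 2.6e-05) and COR15B by 0.66, while COR15A and LTI30 differed by 0.49 and 0.33 (adjusted p = 0.0579 and 0.0661). COR15B lost its call with weights by genotype (adjusted p = 0.0825) and with the plant 3' minus 5' difference as covariate (0.0922; 0.00235 to 0.0922 over all alternatives). LTI30 passed without mbd11 replicate 2 (adjusted p = 0.049; 0.00804 to 0.389 over all alternatives), as did COR15A (0.003; 0.00264 to 0.419 over all alternatives). The list call was lost without mbd11 replicate 1 or 3 (adjusted p = 0.0814 and 0.0621). Auxin genes had a median of 0.43 with 3 higher and 5 over the list alone (camera adjusted p = 0.0931); IAA29 rose by 1.27 and IAA30 by 0.83. The third call, LBD16, differed by 0.48 (adjusted p = 0.0484), a call lost without any single array but mbd6 replicate 2 or mbd11 replicate 3 (adjusted p = 0.059 to 0.123; 0.0103 to 0.231 over all alternatives). Without mbd11 replicate 2 LBD16 differed by 0.30. Root markers had a median of -0.15, and 0.0012 without mbd11 replicate 2, with 1 higher, 1 lower and 3 over the list alone (camera adjusted p = 0.517). PYK10, a root beta-glucosidase gene, fell by 1.73 (adjusted p = 8.7e-06) and EXPA18 rose by 1.08. Flavonoid and anthocyanin genes had a median of -0.53 (camera adjusted p = 0.333), with UGT78D2 lower by 0.62 as the only call in either count. The UGT78D2 call was lost with quantile normalization, at -0.43 (adjusted p = 0.10), weights by genotype (0.104) and the plant 3' minus 5' covariate (0.0711; 0.0016 to 0.104 over all alternatives). These 4 lists come from the same mbd11 arrays, with 3' minus 5' differences of 1.98 to 2.58 against 1.17 to 1.5 in wild type.

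**Figure D2:**
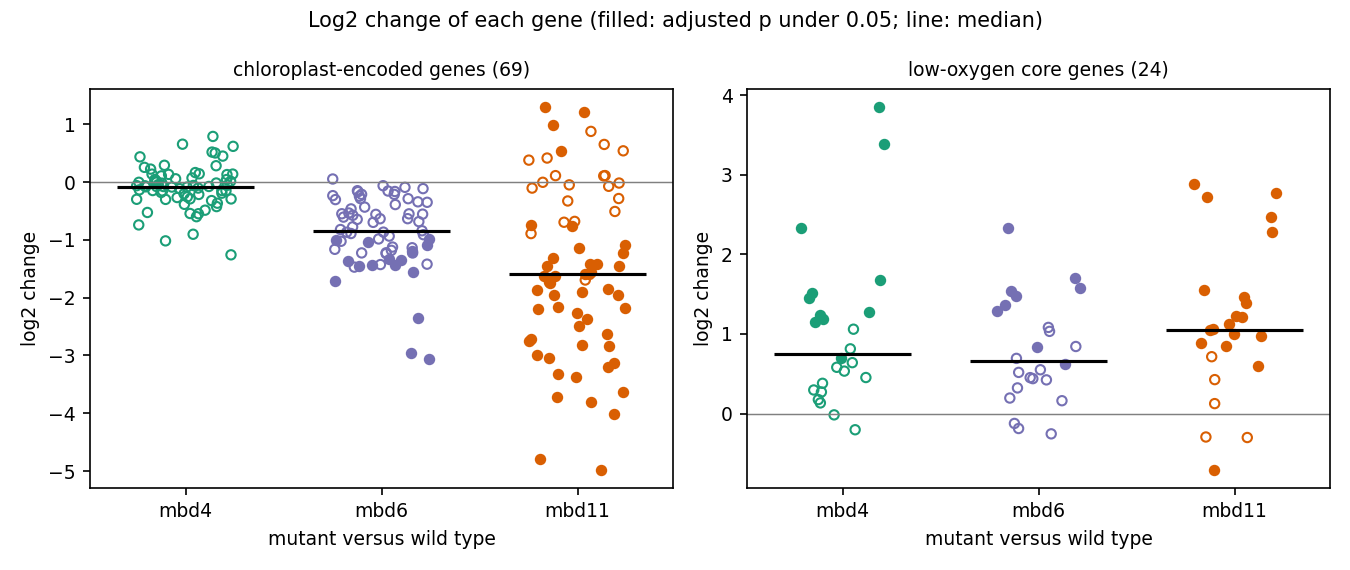
Each point is the change of a gene, mutant minus wild type in log2 units, for 69 chloroplast-encoded and 24 low-oxygen genes in mbd4, mbd6 and mbd11; filled points have an adjusted p under 0.05 and lines are medians. Chloroplast-encoded medians were -0.08, -0.84 and -1.59, and low-oxygen medians 0.75, 0.66 and 1.05.

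Lists with 1 or 2 measured genes were read gene by gene. QQS, an orphan gene known for epigenetic variation, rose by 2.18 in mbd11 (adjusted p = 2.3e-05). It differed by 0.99 in mbd4 and 0.85 in mbd6 (adjusted p = 0.0386 and 0.0406). The mbd4 call was lost without wild-type replicates 1, 2 or 3 (adjusted p = 0.096, 0.183 and 0.093), mbd4 replicates 1, 2 or 3 (0.052, 0.121 and 0.177) or mbd6 replicate 2 or 3 (0.057 and 0.064; 0.000356 to 0.183 over all alternatives). The mbd6 call was lost without wild-type replicates 1, 2 or 3 (adjusted p = 0.083, 0.187 and 0.081), mbd4 replicate 2 (0.065) or mbd6 replicates 1, 2 or 3 (0.196, 0.066 and 0.095; 0.000849 to 0.196 over all alternatives). DME, the DNA glycosylase gene of demethylation, differed by -0.04, 0.07 and -0.16 in mbd4, mbd6 and mbd11 (adjusted p = 1.0, 0.947 and 0.343). The SUMO ligase gene SIZ1 fell by 1.48 in mbd11 (adjusted p = 4.6e-05) and differed by -0.01 and -0.06 in mbd4 and mbd6. STZ rose by 1.74 in mbd11 (adjusted p = 0.000831). CML38 and PAP85 both rose by 1.46 in mbd11 (adjusted p = 0.0068 and 0.00213) and PDF1.2 by 1.15 (0.00234). With the plant 3' minus 5' difference as covariate these 3 calls were lost, at 0.80 for CML38 (adjusted p = 0.251; 9.8e-05 to 0.251 over all alternatives), 0.96 for PAP85 (0.116; 2.3e-06 to 0.116) and 1.09 for PDF1.2 (0.0527; 8.9e-05 to 0.0527). With a floor of 4 PAP85 differed by 0.91 (adjusted p = 0.0612). The clock gene GI fell by 0.70 in mbd11 (adjusted p = 0.0134; 0.052 without wild-type replicate 1, and 0.00322 to 0.0749 over all alternatives; -0.44 without mbd11 replicate 2) and SMZ by 0.45 (0.0111). The GI and SMZ calls were also lost with only the 6 arrays compared (adjusted p = 0.0749 and 0.0862), array weights (0.0517 and 0.0619), weights by genotype (0.0534 and 0.0924) and the covariate (0.0531 and 0.130; SMZ 0.00148 to 0.130 over all alternatives). PRL differed by -0.34, -0.61 and 0.44 (adjusted p = 0.566, 0.0681 and 0.0673).

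In mbd6, STZ differed by 1.39 (adjusted p = 0.016), a call lost without wild-type replicates 1, 2 or 3 (0.070, 0.061 and 0.053) or mbd6 replicate 1 or 2 (0.073 and 0.056; 4.2e-07 to 0.0729 over all alternatives). LPR1 differed by -0.79 in mbd6 (adjusted p = 0.0249), lost without wild-type replicate 2 or 3 (0.124 and 0.088) or mbd6 replicate 1 or 3 (0.118 and 0.094; 0.000387 to 0.124 over all alternatives). PYE differed by -1.15 in mbd4 (adjusted p = 0.0282), lost without wild-type replicates 1, 2 or 3 (0.133, 0.084 and 0.124) or mbd4 replicates 1, 2 or 3 (0.111, 0.118 and 0.087; 3.5e-07 to 0.133 over all alternatives). BHLH101 differed by -1.1 in mbd4 without passing (adjusted p = 0.374). Its mbd4 values, 7.749 to 7.795, lay below its wild-type values, 8.811 to 8.953. The fit pools the spread of all genotypes, and the mbd11 values of BHLH101 were 10.04, 7.80 and 9.87. Spread within mbd11 likewise enters the adjusted p of AT4G33720 and PYE in mbd4 and of STZ in mbd6.

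**Figure D3:**
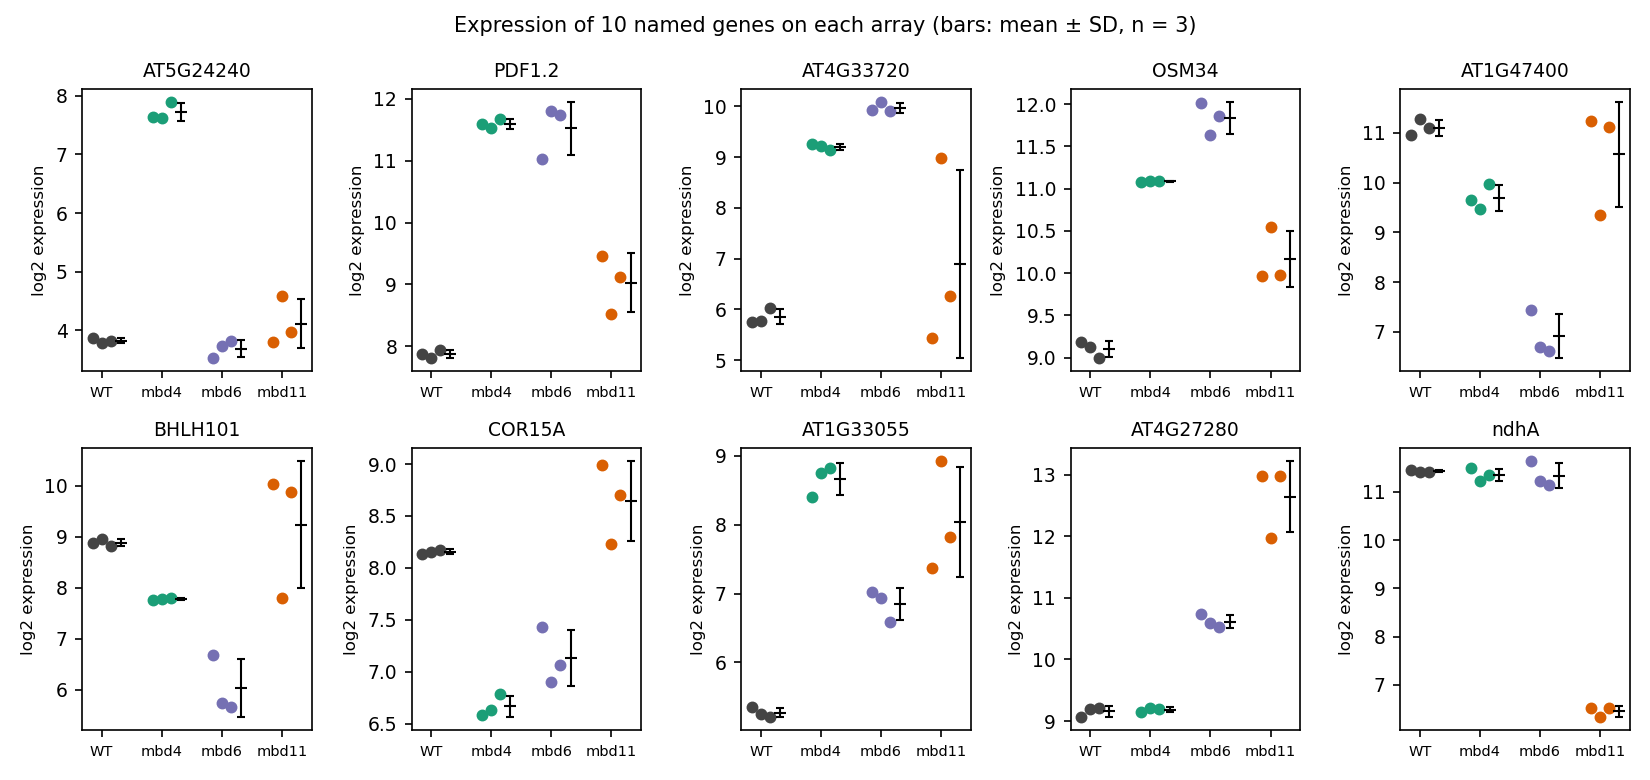
Log2 values of 10 genes chosen after the values were seen; points are arrays, and bars are the mean with SD (n = 3) of wild type, mbd4, mbd6 and mbd11. PDF1.2 has means of 11.59 in mbd4 and 11.52 in mbd6 against 7.88 in wild type, and ndhA has 6.45 in mbd11 against 11.43.

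Tested against each other, mbd6 and mbd4 differed most in AT5G24240, with a difference of -4.03, mbd6 minus mbd4 (adjusted p = 3.4e-07). This gene was under 4 on all mbd6 arrays, and with a floor of 4 the difference was -3.72. Chloroplast-encoded psbI and psbK were lower in mbd6 by 3.67 and 3.46 (adjusted p = 0.000219 and 0.000284), and AT1G47400 by 2.77 (adjusted p = 0.00376). AT3G19680, AT1G76960 and AT1G26250 were higher in mbd6 by 2.43, 2.38 and 2.30 (adjusted p = 0.000186, 4.7e-05 and 0.0011). AT1G26250 was under 4 on all mbd4 arrays, and with a floor of 4 its difference was 1.98. PDF1.2 differed by -0.08 (adjusted p = 0.999), AT4G33720 by 0.77 (0.81) and BHLH101 by -1.75 (0.0802). The moderated test called 467 probe sets, 216 higher and 251 lower in mbd6, with 189 at least 2-fold. No overlap was seen for 28% of all probe sets, beside 10% by chance. The count was 268, 277 and 263 without wild-type replicates 1 to 3, and 160, 161 and 171 without mbd4 replicates 1 to 3. It was 190, 177 and 157 without mbd6 replicates 1 to 3, and 1638 and 724 without mbd11 replicates 2 and 3. Without all mbd11 arrays it was 2470.

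Against mbd4, mbd11 had higher AT2G15010 and AT3G02480, both by 3.52, and AT4G27280 by 3.46; ndhA, rpl36 and petB were lower by 4.90, 4.27 and 4.0. AT2G15010 was under 4 on all mbd4 arrays, and its difference was 2.81 to 4.67 over all alternatives. COR15A and COR47 were higher in mbd11 than in mbd4 by 1.98 and 1.59, and PDF1.2 was lower by 2.56 (adjusted p = 1.4e-05). Against mbd6, mbd11 had higher AT3G02480 by 3.83, AT1G47400 by 3.65 and AT1G73120 by 3.58. AT3G02480 was under 4 on all mbd6 arrays, so its size and rank rest on dim values (3.51 to 4.09 over all alternatives). BHLH101 was higher in mbd11 by 3.21 (adjusted p = 0.000208), and ndhA, rpl36 and AT5G13030 were lower by 4.88, 4.19 and 3.8. Between mbd11 and mbd4, 9621 probe sets were called, 5116 higher and 4505 lower, with a median of 0.13; median centring gave 6695 higher and 3740 lower. Between mbd11 and mbd6, 9636 were called, 5120 higher and 4516 lower, with a median of 0.13; median centring gave 6954 higher and 3762 lower. Only the 6 arrays compared gave 4510 calls against mbd4 and 5069 against mbd6, and weights by genotype 5002 and 5261. The plant 3' minus 5' difference as covariate gave 5790 against mbd6. That difference was 1.98 to 2.58 in mbd11, 1.08, 1.15 and 2.08 in mbd4 and 1.2 to 1.3 in mbd6. No overlap was seen for 46.6% and 48.8% of all probe sets, beside 10% by chance.

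A set of genes was called in the same direction in all 3 mutants. AT1G65500 rose by 1.91, 1.98 and 1.96 in mbd4, mbd6 and mbd11. AT2G43620 rose by 2.16, 1.75 and 1.73, AT1G19530 by 3.85, 1.70 and 2.47, AT1G23140 by 1.85, 2.37 and 1.60, and AT3G29970 by 1.51, 2.34 and 1.55. AT2G15020 fell by 1.36, 2.1 and 1.44, AT2G40460 by 1.37, 1.13 and 1.09, AT5G15950 by 1.07, 1.16 and 1.93, and AT1G48100 by 1.04, 2.06 and 2.08. The cytokinin response regulator gene RR16 fell by 0.99, 1.54 and 1.16. In all, 166 probe sets were called higher and 67 lower in all 3 mutants, where 2.85 and 1.01 were expected from the counts alone. The same 3 wild-type arrays enter all 3 changes. Without wild-type replicates 1, 2 or 3 the counts were 89, 101 and 83 higher and 29, 29 and 27 lower.

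Between mbd4 and mbd6, 360 probe sets were called in the same direction, 255 higher and 105 lower, and 3 in opposite directions, where 19.0 in the same direction were expected from the counts alone. Their changes correlated with r = 0.66, beside 0.41 in simulations that share only the wild-type arrays, because the same 3 wild-type arrays enter both changes. Leaving out wild-type replicates 1, 2 or 3 gave 184, 197 and 179 shared calls. Of the 360, 41 also differed between mbd6 and mbd4, and in mbd11 233 were called in the same direction and 26 in the opposite direction.

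Between mbd4 and mbd11, 311 probe sets were called in the same direction, 217 higher and 94 lower, and 48 in opposite directions, with 106 expected (r = 0.25, simulated 0.18). Without wild-type replicates 1, 2 or 3 the shared calls were 157, 170 and 153. Between mbd6 and mbd11, 787 were called in the same direction, 449 higher and 338 lower, and 167 in opposite directions, with 317 expected (r = 0.28, simulated 0.21). Without wild-type replicates 1, 2 or 3 the shared calls were 416, 433 and 373.

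**Figure D4:**
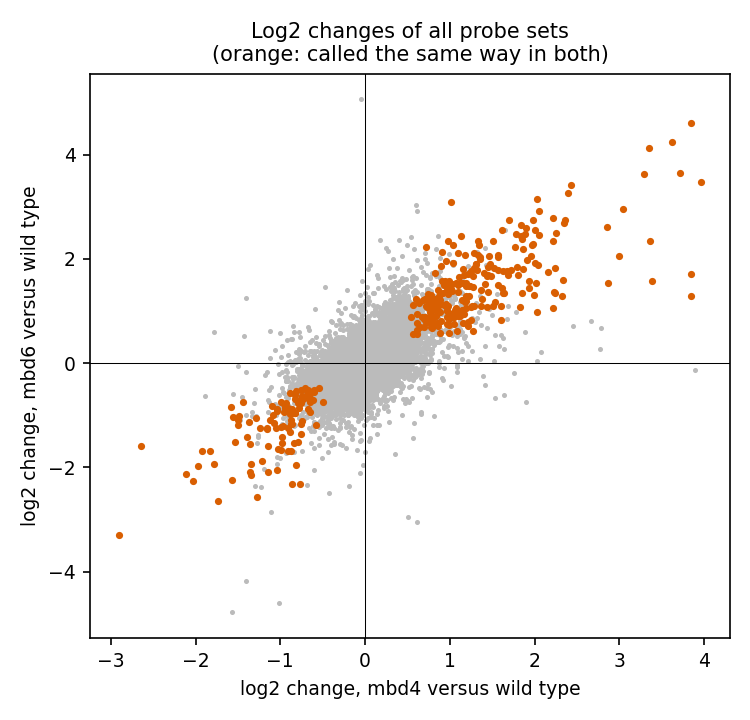
Each point is a probe set, with its change in mbd4 on the horizontal axis and in mbd6 on the vertical axis, both mutant minus wild type in log2 units. Orange points are the 360 called in the same direction in both (255 higher, 105 lower), and r over all probe sets was 0.66.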

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

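The tests of the mbd11 calls without replicate 2, of the bacterial controls, of the covariance between mutants and of wild type set apart were chosen only after the result was seen. The others were written before their outcome was known.

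Affymetrix control probe sets report both ends of a few plant and bacterial transcripts. The 3' minus 5' difference was higher in all 3 mbd11 arrays than in all 3 wild-type arrays for 6 of the quantities checked. Mean differences, mbd11 minus wild type, were 2.32 for GAPDH, 2.37 for the second actin pair and 1.16 for the second GAPDH pair. They were 0.15 for ubiquitin, 1.95 for dap and 1.70 for thr. The first actin pair averaged 3.25 in mbd11 and 3.52 in wild type, and the second ubiquitin pair 0.02 and 0.38, so not all pairs were raised. With 9 quantities in 3 mutants, 27 were checked, and each has a chance of 1 in 20 of such an ordering.

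Of all probe sets, 9141 were called in mbd11, and over all probe sets the mbd11 change correlated with mbd4 replicate 3 minus mbd4 replicates 1 and 2 at r = 0.209, a contrast with a raised 3' minus 5' difference inside a genotype. A covariate for that difference left 5829 calls. Replicate 2 alone is excluded as the sole source, because 10057 were called without it and 8207 of the reported ones stayed in the same direction. The lowest mbd11 value of the mean 3' minus 5' difference of dap and thr lay 1.04 above the highest wild-type value. Their 3' signals rose as well, thr to 6.95 to 7.31 in mbd11 from 5.21 to 5.63 in wild type. The 3' signal of dap was 6.73 to 7.95 in mbd11 and 6.04 to 6.46 in wild type. For dap the mean 3' signal went from 6.21 in wild type to 7.39 in mbd11, while its 3' minus 5' difference rose by 1.95. The mean 5' signal of dap was therefore lower in mbd11. For thr the 3' signal rose by about as much as the difference, so its mean 5' signal was about unchanged. Because dap and thr disagree here, loss of 5' ends limited to plant RNA cannot be excluded by them. RNA handling and labelling, or the mutation itself, may lie behind the calls; they cannot be told apart here, because all mbd11 arrays and no wild-type array carry the difference.

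The 989 pseudogene probe sets had a median change of 0.39 in mbd11, with 276 higher and 3 lower (camera adjusted p = 1.9e-08; 0.736 with an estimated correlation), beside -0.05 in mbd4 and -0.04 in mbd6 (0.523 for each). Probe sets of other genes matched for wild-type level had a median of 0.40 in mbd11, 0.36 to 0.43 over 1000 draws. The excess of pseudogenes was -0.012, which argues against a release of pseudogenes as such, and raised low values remain a possible account. In 5 classes of rising wild-type level, the median mbd11 change was 0.40, 0.29, -0.03, -0.23 and -0.38. Without replicate 2 a share of 0.538 of the pseudogene median was left (95% bootstrap range over probe sets 0.487 to 0.572). That range does not cover the spread between arrays, because only probe sets were drawn again. Replicate 2 and the other mbd11 arrays cannot be told apart as the source of the pseudogene median, because both hold part of it.

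Changes in mbd4 and mbd6 had 360 shared calls in the same direction. Their covariance was 0.0818, and the highest value in 100 simulations of shared wild-type arrays was 0.0084. The simulated noise was independent for each probe set, so only such noise is excluded as the whole account. Noise shared across probe sets was not simulated and is not excluded. Deviations from the group mean in wild-type replicate 2 and mbd4 replicate 3 correlated at 0.507. Of the shared calls, 82.8% had the same sign in mbd11, where the median change in the shared direction was 0.83, against 1.19 in mbd4 and mbd6, a ratio of 0.699. Because the same wild-type arrays enter all these changes, shared calls were also chosen without each wild-type array in turn and measured against that array, which gave ratios of 0.625, 0.677 and 0.624 with 82.6%, 81.2% and 82.1% of the same sign. Wild-type seedlings set apart from all mutants by growth or handling would give such ratios, and so may an effect shared by the mutants; both remain open because there is a single set of wild-type seedlings.

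Relabelling the 6 arrays of a comparison gives 10 splits, and the real one ranked 1 of 10 in each comparison. The real counts were 523, 1572, 9141, 467, 9621 and 9636, against 0 in every other split. With 10 splits no share under 0.05 can be reached.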

How the results depend on the processing

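Results in this part marked as added were chosen after seeing the data. The number of arrays, 3 per genotype, limits the precision of every value. Counts are given in the order mbd4, mbd6 and mbd11 against wild type, mbd6 against mbd4, mbd11 against mbd4 and mbd11 against mbd6, where the reported counts were 523, 1572, 9141, 467, 9621 and 9636. Without the dimmest 25%, with a floor of 4, quantile normalization, median centring, or trend and robust moderation, all 6 stayed within 1.5 times. Fits of only the 6 arrays compared gave 2004, 4535, 5100, 1779, 4510 and 5069. Array weights gave 3842, 5367 and 3822 for mbd4, mbd6 and mbd6 against mbd4. A 2-fold minimum left 263, 631, 2922, 189, 2917 and 2982. Testing only probe sets of 1 gene left 209, 676, 5136, 165, 5454 and 5485, where fewer probe sets were tested. Among added alternatives, weights by genotype gave 2389, 4880, 5262, 2463, 5002 and 5261. In simulation 29.5%, 16.4% and 47.4% of calls with these weights were false in mbd4, mbd6 and mbd11. Those shares depend on the few probe sets shifted there and are not estimates for the real calls. Leaving out mbd11 replicate 2 and mbd4 replicate 3 gave 1139, 3476 and 1210 for mbd4, mbd6 and mbd6 against mbd4. Leaving out the mbd11 arrays gave 2212, 4106 and 2470 for these, and 3083, 5457 and 3287 with the plant 3' minus 5' difference as covariate. That covariate alone gave 5829 for mbd11 and 5790 for mbd11 against mbd6.

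Leaving out each array in turn gave 259 to 1464, 807 to 3155, 6906 to 10757, 157 to 1638, 6877 to 11173 and 6980 to 11113 calls. For shared calls (360 of mbd4 and mbd6, 311 of mbd4 and mbd11, 787 of mbd6 and mbd11), leaving out each wild-type array gave 179 to 197, 153 to 170 and 373 to 433. A 2-fold minimum left 170, 115 and 233 shared calls. Weights by genotype gave 1503, 689 and 1326, and leaving out the 2 outlying arrays gave 781, 585 and 1708. Without the mbd11 arrays mbd4 and mbd6 shared 1328. Where these alternatives moved a count, the cause was not tested, except that a stricter minimum lowers counts by construction. The fit pools the spread of all genotypes. The wider mbd11 spread therefore enters the mbd4 and mbd6 counts of fits that hold unweighted mbd11 arrays. Its median SD was 0.353, against 0.112 in wild type, 0.134 in mbd4 and 0.118 in mbd6.

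With the replicate number as a block the counts were 435, 1360, 8811, 315, 9242 and 9221, and shared calls 298, 259 and 686. Same-numbered samples of different genotypes correlated at -0.38 to 0.22, over 0.1 in 3 of 18 pairs, and 2 of 12 samples correlated best with their own number. The block changed the calls of COR47 in mbd4 (adjusted p = 0.058), QQS in mbd4 and mbd6 (0.067 and 0.064) and LBD16 in mbd11 (0.071), and none in the 24 tests of lists fixed beforehand; further lists were not tested with the block.

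Named genes gave 4875 alternative values over 194 gene comparisons: 4668 kept direction and side of the threshold, 149 lost the call, 55 gained it and 1 reversed. The other 2 were of AT5MAT in mbd6, not called at 0.15, which was -0.04 with array weights and -0.23 without mbd6 replicate 1 (adjusted p = 0.923 and 0.929). The cause was not tested. The reversal of a called gene was a change of sign without a call. It was that of psaA in mbd11 with the plant covariate, at 0.0074 (adjusted p = 0.997) against -3.63 as reported. In mbd4 replicate 3, an array with a raised 3' minus 5' difference, psaA was at 4.05, against 9.71 and 8.82 in the other mbd4 arrays. The cause was not tested further. Of 24 list tests, 12 passed with the preset correlation and 1 with the estimated correlation. With fry, which tests a list on its own, 5 list results gained a call and 1 lost it; with all probe sets of a gene none changed. The transposable element test was not run.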

Other observations

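The gene groups in this part were chosen after values were seen, and each was tested with camera over 111 tests. Transcripts of the low-oxygen core response rose in mbd4 and mbd6, with 11 and 9 of 24 genes higher and 0 lower. Their median changes were 0.75 and 0.66 (camera adjusted p = 1.0e-22 and 6.8e-12; 0.0049 and 0.0246 with an estimated correlation). In mbd11 18 were higher and 1 lower, with a median of 1.05 (camera adjusted p = 7.1e-06; 0.0947 with an estimated correlation). AT4G27450 rose by 1.45, 1.36 and 0.88 in mbd4, mbd6 and mbd11, AT1G74940 by 0.69, 0.84 and 1.00, and AT4G33560 by 1.68 in mbd4 and 2.29 in mbd11. The pyruvate decarboxylase gene PDC2 was the one that fell, by 0.71 in mbd11 (adjusted p = 0.0029). The mbd11 arrays had plant 3' minus 5' differences of 1.98 to 2.58, against 1.17 to 1.5 in wild type.

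Class III peroxidase genes had 15 higher and 6 lower of 47 in mbd6, with a median change of 0.23 (camera adjusted p = 0.000524; 0.0475 with an estimated correlation). Prx37 rose by 2.22 in mbd4 (adjusted p = 0.0048) and 2.34 in mbd6 (0.0017), AT5G19890 by 1.77 and 2.24, AT4G11290 by 1.73 and 1.79, and PRX52 by 2.00 in mbd6 (0.00074), where AT5G15180 fell by 1.04. Peroxidase medians were 0.03 in mbd4 with 6 higher and 1 lower (camera adjusted p = 0.0824). In mbd11 the median was -0.06 with 5 higher and 11 lower (camera adjusted p = 0.383), and 0.04 with 5 higher and 10 lower after median centring. Core histone genes had 7 of 9 higher in mbd11, with a median of 0.62 (camera adjusted p = 0.0189; 0.689 with an estimated correlation), HTB2 rising by 0.92, on arrays with 3' minus 5' differences of 1.98 to 2.58 against 1.17 to 1.5 in wild type. Their medians were -0.02 in mbd4, and 0.0005 with quantile normalization, and -0.02 in mbd6 (camera adjusted p = 0.822 and 0.695).

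Among families of shared symbol, 1, 2 and 3 of 28 passed in mbd4, mbd6 and mbd11, and 0 passed with an estimated correlation. The small-peptide family RALFL had 7 of 11 higher in mbd11 with a median of 0.91 (camera adjusted p = 0.000538; 0.0947 with an estimated correlation), RALFL22 rising by 1.71. Aldehyde dehydrogenase genes (ALDH) had 6 of 8 lower in mbd11 with a median of -0.60 (camera adjusted p = 0.00243; 0.238 with an estimated correlation), ALDH22A1 falling by 1.21. Autophagy genes (ATG) had a median of 0.22 in mbd4 and 0.25 in mbd6 over 8 (camera adjusted p = 0.0278 for each; 0.71 with an estimated correlation), ATG8E rising by 0.82 and 0.88. BZIP genes had a median of 0.24 over 14 in mbd6 (camera adjusted p = 0.028; 0.487 with an estimated correlation). The mbd11 families come from arrays with 3' minus 5' differences of 1.98 to 2.58, against 1.17 to 1.5 in wild type.

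Extended cytosolic ribosomal genes (112) had medians of 0.05, -0.17 and 0.03 in mbd4, mbd6 and mbd11, the last with 28 higher and 20 lower, and -0.03 with 11 higher and 15 lower with the 3' minus 5' covariate. Their camera adjusted p was 0.135, 5.0e-05 (0.71 with an estimated correlation) and 0.86. Nuclear genes for chloroplast ribosomal proteins (9) had medians of -0.06, -0.40 and -0.36 (camera adjusted p = 0.972, 0.095 and 0.147). Mitochondrion-encoded genes (16) had 0.18, -0.12 and 0.40 (camera adjusted p = 0.138, 0.379 and 0.315).

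A hypothesis that low-oxygen genes rise together was tested on the 18 members whose values had not been seen, leaving out 6. Their medians were 0.56, 0.48 and 0.93 in mbd4, mbd6 and mbd11, with 6, 4 and 12 higher and 0, 0 and 1 lower. The highest camera adjusted p over the mutants was 0.000672, and 0.00936 with an estimated correlation. The unseen members may share a response to low oxygen or to handling of the seedlings. They were read on the same arrays as the seen members. The same 3 wild-type arrays enter all 3 changes, so the mutants are not independent tests. Wild-type seedlings set apart from all mutants remain possible here too. A second hypothesis, that iron deficiency genes fall together in mbd6, was tested on 8 unseen members, leaving out 5. Their median was -0.18 (camera adjusted p = 0.695), and the hypothesis did not pass. With all 13 genes, seen ones included, 5 were lower in mbd6, with a median of -0.37 (camera adjusted p = 6.3e-05; 0.625 with an estimated correlation). In mbd4 the median was -0.15 with 1 lower (camera adjusted p = 0.0316; 0.724 with an estimated correlation). In mbd11 it was 0.18 with 3 higher and 1 lower (camera adjusted p = 0.84), and -0.05 with 3 higher and 0 lower with quantile normalization.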
